A study of Bifidobacterium breve UCC2003 and Bifidobacterium breve with 6 samples.

How the data were processed

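Transcript levels of Bifidobacterium breve UCC2003 were measured on 6 2-colour Agilent oligonucleotide arrays, on 3 slides. Each array carried RNA recorded as coming from cells grown on a named sugar in 1 channel and RNA recorded as coming from cells grown on ribose in the other. Melibiose, melezitose, raffinose and stachyose had 1 array each, and sucrose had 2, the second of which the labels name as a dye swap of the first. On 5 arrays the labels put the sugar in Cy3 and ribose in Cy5, and on the second sucrose array the dyes were exchanged. The 2 sucrose arrays were averaged into 1 replicate, so that each sugar had 1 replicate. Nothing in the labels says that the cultures were grown separately, so p-values measure only the spread between these sugars and arrays, part of which may be technical.

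The scans were quantified by the authors with Agilent Feature Extraction 9.5, per the submitters' processing notes. The deposited scanner files give, per spot and channel, the intensity of the spot and of its local background without normalization. Per the file headers, the same software also wrote processed intensity values after background subtraction, detrending and dye normalization, and their log10 ratio of Cy5 over Cy3. The authors' deposited value table holds log10 ratios, 1 column per array, each within 0.001 of the scanner's log10 ratio turned to sugar over ribose by the labels' dyes. By this match its scale, centring and direction are those of the scanner's ratio. Its median was 0 on all 6 arrays, and 773 to 3777 spots per array had a value of 0. The flags of the deposited files, other values without a unit, mark spots well above background, saturated spots and outliers. The series' design text names a regularised t-test and cutoffs of a ratio above 3 or below 0.33.

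Starting from mean spot and median background intensity, the background was corrected with normexp (offset 50) and each array was normalized by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Control spots and outlier spots had weight 0. Of 10807 spots per array, 10129 belonged to 5589 probes for 1863 genes, namely 1843 locus tags and 20 tRNA genes. Spots were averaged per probe and the 3 probes of a gene per gene, and the SD over probes was kept as a within-array spread. No spot was saturated. The number of arrays limits the precision. Array levels per channel were taken after loess and Aquantile scaling. Where no spot of a gene was well above background in the dimmer channel, the fold is given as "at least", from the brighter channel against the higher of the lowest spot well above background and the gene's own value. Folds between sugars compare levels within the channel recorded as ribose by the same rule, a comparison added after the data were seen. With the dye exchanged on 1 array only, such bounds are open to dye bias.

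Single sugars were described by genes past 3-fold, without a test. Both tested comparisons were fitted with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg 0.05). The first set the mean log2 ratio of the 5 sugars against 0. Its spread includes that of the channel recorded as ribose between arrays. If all arrays shared a ribose extract, the spread between ribose cultures is left out. The second compared the 3 sugars with an alpha-1,6-galactosyl unit (melibiose, raffinose and stachyose) with sucrose and melezitose. On simulated data with the real genes' spread, 1863 genes and 200 changed ones, the first called 94.5% of 2-fold and 99.5% of 4-fold changes. The second called 46.7% of 2-fold and 93.2% of 4-fold changes. Simulated changes were alike on all sugars that carried them, with independent noise at the spread left by the second fit. Changes that differ in size between sugars are therefore not covered by these shares. In the real data Bbr_0027, at a mean of 6.23-fold over the 5 sugars, was not called (limma adjusted p = 0.0885). Between the classes Bbr_1869, at 6.47-fold, was not called (limma adjusted p = 0.984). With 200 changed genes the Benjamini-Hochberg cutoff is also looser than where few loci are called. The shares may therefore be too high for the real data.

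The files identify genes by locus tag only. The reference table used here is of another strain of the species, and 0 of the 1843 locus tags matched it. The files therefore do not pair the tags with gene names or functions, and the 17 functional gene lists chosen before the data were examined were not run. For the same reason few loci or runs of consecutive locus tags are named, some of them on several sugars. They come from a rule set beforehand: per sugar the 8 highest and 8 lowest ratios among genes well above background in a channel on at least 50% of probes and with the same sign on every probe, per tested comparison the 12 largest changes each way, and neighbours in the same run. Probes for 6 loci were identical in pairs, and none of these loci is named. Probes for spike-ins, plasmids and other named items, 25 names in all, were left out of the gene tests.

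Alternatives tried were the scanner's processed ratios, the authors' value table, no background correction, offset 10, median centring, Aquantile, a filter on dim probes, the median over probes, subtraction of the dye effect, each sucrose array alone, both as separate samples with a dye term, the slide as a block, leaving out each sugar, an intensity trend with robust eBayes, and the methods' t-test over probes within an array, with prior settings chosen here.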

Results

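The 6 arrays compared transcript levels of Bifidobacterium breve UCC2003 on 5 sugars with those on ribose. The sugars are alpha-glycosides that differ by single units. Sucrose is a glucosyl-fructoside, raffinose is sucrose with a galactosyl unit, and stachyose carries a further galactosyl unit. Melibiose is raffinose without its fructosyl unit, and melezitose is sucrose with a further glucosyl unit. The share of spots well above background ranged from 39.6% to 78.6% in the channel recorded as sugar and from 28.4% to 99.97% in the channel recorded as ribose, the highest value being that of the stachyose array. Each sugar had 1 replicate, so ratios of single sugars have no replicate check, and the SD given with them is that over the 3 probes of a gene.

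The direction of the ratios is not settled. Over 1863 genes, the channel recorded as sugar correlated more between arrays (median r = 0.968) than the channel recorded as ribose (median r = 0.907), and did so for 15 of 15 pairs of arrays. Genes are not independent replicates, so these r values only describe the arrays. Of 93 loci past 3-fold on at least 1 sugar, 86 varied more over the 5 sugars in the channel recorded as ribose, as did 1419 of all 1863 genes (76.2%). Ratios are therefore given as recorded, sugar over ribose, with the channel in which a locus was brighter. If both channels were exchanged on every array, each sign turns and the sizes stand. The authors' deposited table has the recorded direction.

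The run Bbr_1415 to Bbr_1419 was brighter in the channel recorded as sugar on all 5 sugars. The difference between the channels was 15.2 to 18.3-fold over its 5 loci on melibiose and 7.93 to 14.5-fold on stachyose. On melibiose only 1 of 6 spots of Bbr_1415 and 1 of 5 spots of Bbr_1416 were well above background in the channel recorded as ribose. On melezitose no spot of the run was well above background in that channel. There the difference was at least 66.5-fold for Bbr_1418 and at least 33.8-fold for Bbr_1416. For Bbr_1416 the mean log2 ratio was 4.55 ± 1.03 (SD, n = 5; limma adjusted p = 0.00332). Its log2 level in the channel recorded as sugar was 12.11 on melibiose, 12.69 on melezitose, 12.37 on raffinose and 12.25 on stachyose, and in the other channel it lay between 6.48 and 8.80 on the 6 arrays. The ratios of Bbr_1416 on melezitose, raffinose and sucrose, and so its mean, rest on a channel recorded as ribose that was not well above background, as do those of Bbr_1425 on all sugars but stachyose. Bbr_1425, a few loci away, was called with a smaller mean log2 ratio of 1.59 ± 0.26 (SD, n = 5; limma adjusted p = 0.00332), and on melibiose it was at least 2.47-fold brighter in the channel recorded as sugar.

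In all, limma called 8 loci over the 5 sugars as brighter in the channel recorded as sugar, all from Bbr_1415 to Bbr_1425. By sign each was so in 5 of 5 sugars. On sucrose, however, Bbr_1421 had no usable fold and Bbr_1424 was only at least 1.04-fold brighter. Limma called 0 as brighter in the channel recorded as ribose. At an unadjusted p under 0.05 there were 130 and 88. The scanner's processed ratios called 0 and 0, with an adjusted p of 0.151 for each of the 8. Median centring called 8 and 5, and the slide as a random block called 15 and 8.

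**Figure D1:**
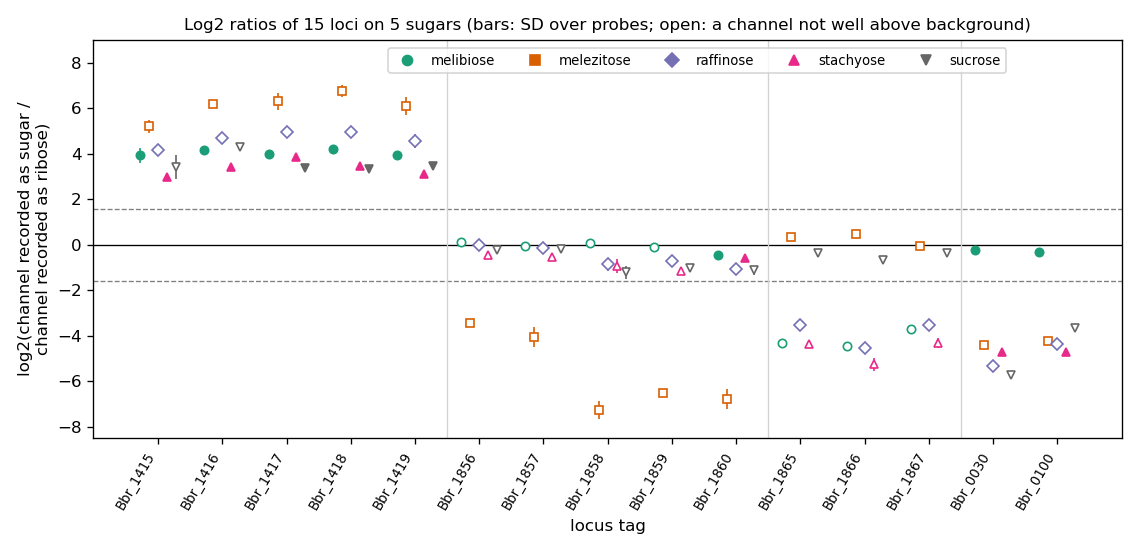
Log2 ratio of the channel recorded as sugar over the channel recorded as ribose (y axis) for 15 loci in locus tag order within 4 sets (x axis). Points are sugars, bars are the SD over the probes of a gene, open symbols have a channel not well above background, dashed lines mark 3-fold, and grey lines part the sets. Bbr_1415 to Bbr_1419 lie above 3-fold on 5 sugars, and Bbr_1858 lies at -7.26 on melezitose, a difference of at least 68.2-fold.

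On melezitose the run Bbr_1855 to Bbr_1860 was brighter in the channel recorded as ribose. Its largest log2 ratio was -7.26 ± 0.39 (SD over probes), at Bbr_1858, a difference of at least 68.2-fold. The level of Bbr_1858 in the channel recorded as ribose was 13.8 on the melezitose array and 7.27 to 8.04 on the other 5, while in the channel recorded as sugar it lay between 6.60 and 7.35 on all 6. On melibiose, raffinose and sucrose Bbr_1858 had no usable fold, since it was dim in both channels or its bound lay under 1. On the same array Bbr_1847 had a log2 ratio of 2.92 ± 0.01 (SD over probes), against 0.78 on stachyose, -0.89 on raffinose, -2.42 on melibiose and -2.69 on sucrose. In all, 26 loci passed 3-fold on melezitose, 15 brighter in the channel recorded as sugar and 11 in the other.

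The 3 galactosides shared the run Bbr_1865 to Bbr_1867, brighter in the channel recorded as ribose. In that channel Bbr_1866 was at least 10.2-fold brighter on the galactosides than on sucrose and melezitose, Bbr_1865 at least 7.16-fold and Bbr_1867 at least 5.05-fold. On sucrose and melezitose no spot of the 3 loci was well above background in either channel, and on the galactosides none was in the channel recorded as sugar, so the fitted ratios below rest partly on signals near background. For Bbr_1866 the mean log2 ratio was -4.74 ± 0.45 (SD, n = 3) on melibiose, raffinose and stachyose and -0.08 ± 0.80 (SD, n = 2) on sucrose and melezitose. The fitted difference was -4.65 (SE 0.43; limma adjusted p = 0.0334). It was -4.07 for Bbr_1865 and -3.65 for Bbr_1867, both with a limma adjusted p of 0.0334. Each of the 3 galactosides lay below both other sugars. Within the slide that held melibiose and melezitose, Bbr_1866 differed by -4.92, which is also its value with the slide as a fixed block. The other slides held no such pair.

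These 3 loci were the ones limma called between the classes, with 0 called the other way. At an unadjusted p under 0.05 there were 10 and 9. Together these are under a share of 0.05 of the 1863 genes, so the lack of other calls does not show that other loci were alike. The scanner's processed ratios called 0, with adjusted p from 0.217 to 0.376 for the 3 loci. Leaving out melibiose, melezitose, raffinose or stachyose also left 0 of the 3 called, and leaving out sucrose left 1. With the slide as a fixed block the difference is that of melibiose and melezitose alone, 1 array each. Its spread then comes from raffinose against stachyose, so calls of that fit are no result for the classes. With the slide as a random block 3 loci were called in this direction and 0 in the other.

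Bbr_0030 and Bbr_0100 were brighter in the channel recorded as ribose on the 4 sugars that carry a fructosyl unit. For Bbr_0030 the difference was at least 19.99-fold on melezitose, at least 30.4-fold on raffinose, 26.0-fold on stachyose and at least 28.7-fold on sucrose, and its log2 ratio was -0.21 on melibiose. For Bbr_0100 it was at least 15.1-fold on melezitose, at least 15.8-fold on raffinose, 26.2-fold on stachyose and at least 10.1-fold on sucrose, and the log2 ratio was -0.30 on melibiose. The bounds stand where no spot was well above background in the channel recorded as sugar. Over the 5 sugars neither was called (limma adjusted p = 0.111 for each).

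**Figure D2:**
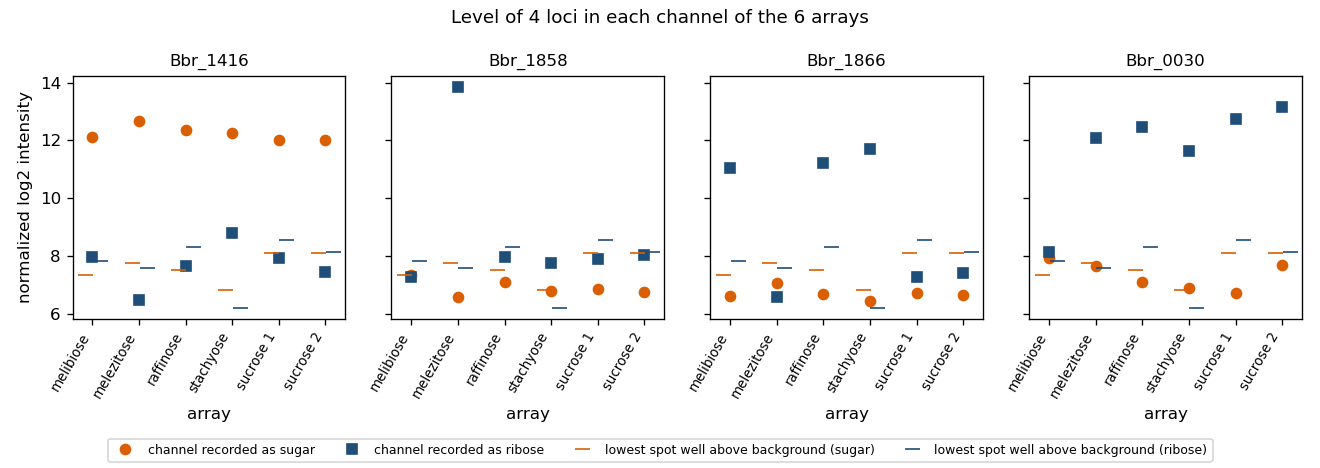
Normalized log2 intensity (y axis) of 4 loci in each channel of the 6 arrays (x axis), 1 panel per locus. Circles are the channel recorded as sugar, squares the channel recorded as ribose, and short lines the lowest spot well above background in each. Bbr_1858 reaches 13.8 in the channel recorded as ribose on the melezitose array, and Bbr_0030 in that channel lies at 8.14 on melibiose and at 11.6 or more on the other arrays.

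The counts of loci past 3-fold on each sugar include those described above. On sucrose 39 passed, 9 brighter in the channel recorded as sugar and 30 in the other. They included the run Bbr_1898 to Bbr_1901, at 3.21 to 3.48-fold for its last 3 loci in the channel recorded as sugar, and Bbr_0027, with a log2 ratio of -4.46. Bbr_1898 also passed on raffinose (log2 ratio 1.69) and, the other way, on melezitose (-2.08). On melibiose 35 loci passed, 7 and 28, among them the run Bbr_1878 to Bbr_1880, 6.16 to 7.87-fold brighter in the channel recorded as ribose. This run also passed on sucrose, 9.85-fold for Bbr_1879 and at least 6.65-fold for Bbr_1880. On stachyose 48 passed, 12 and 36, among them Bbr_0690 and Bbr_0691 at log2 ratios of -3.03 and -3.40. Most of the 36 lay towards the ends of the locus tag order, a pattern by position described further below for this array. They may therefore not be separate results for single loci. Stachyose ratios of other loci there, Bbr_0030, Bbr_0100 and Bbr_1865 to Bbr_1867 included, may hold part of this pattern. On raffinose 18 passed, 8 and 10.

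Median centring in place of loess gave 8 and 11 on melibiose, 11 and 9 on raffinose and 44 and 112 on stachyose. The scanner's processed ratios gave 57 and 67 on melibiose and 25 and 46 on sucrose. Loci past 3-fold tended to lie beside each other in locus tag order. On sucrose 27 of them had a neighbouring tag past 3-fold the same way, against a maximum of 10 in 10000 random draws, and on raffinose 10 did, against a maximum of 4.

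The 2 sucrose arrays give the technical spread of that pair. Their ratios correlated with r = 0.932 over genes once turned the same way, the SD of their difference was 0.20 on the log2 scale, and 0 genes differed by over 3-fold. This is no measure of the spread between cultures. These arrays also had the highest negative controls, with medians of 327 to 599 against 108 to 218 on the others. The technical spread on the other arrays may therefore be larger. Differences between sugars that differ by a single unit follow, as counts of loci whose ratios lay over 3-fold apart and as levels in the channel recorded as ribose. Raffinose and sucrose, which differ by a galactosyl unit, had 16 such loci, of which 12 were well above background in a channel on both sugars. Among the 16, Bbr_1866 was at least 7.29-fold brighter on raffinose, and Bbr_1880 was 4.01-fold brighter on sucrose. Stachyose and raffinose had 38, of which 22 were well above background on both, among them Bbr_0691, 11.3-fold brighter on stachyose. This count may include the pattern by position on the stachyose array. Raffinose and melibiose, which differ by the fructosyl unit, had 14, all well above background on both. In this pair Bbr_0030 was 19.9-fold brighter on raffinose, with 4 of its 6 spots well above background on melibiose. Melezitose and sucrose, which differ by a glucosyl unit, had 74, of which 59 were well above background on both. Here Bbr_0366 was at least 20.1-fold brighter on sucrose. Bbr_1858 was 45.4-fold brighter on melezitose against the lowest spots well above background on sucrose, where 1 of its 8 spots was. With 1 replicate per sugar these differences were not tested, and the unit cannot be told apart from the arrays and cultures.

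Over genes, melibiose correlated with sucrose (r = 0.744) and raffinose (r = 0.690) and not with melezitose (r = 0.00), with which it shared a slide. If all arrays had shared a ribose extract, unchanged groups simulated with the spread of the sucrose pair would give r = 0.502 and a covariance of 0.0098. That r follows from giving control and groups the same spread, whatever its size, so it is no yardstick for the observed r. The observed covariance was 0.215 for melibiose and sucrose. Part of the observed r and covariance may come from a shared control. The simulation cannot bound that part, since a deviation of the control common to both sucrose arrays cancels from their difference. Melibiose and sucrose had 19 loci in common past 3-fold in the channel recorded as ribose, where independent lists would share 0.45. On all 5 sugars 6 loci passed the same way, the run Bbr_1415 to Bbr_1419 and Bbr_0027. Bbr_0027 fell short of 3-fold on melibiose with median centring (log2 ratio -1.22) and without background correction (-1.52), on melezitose without background correction (-1.54) and on stachyose with median centring (-1.45).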

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

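All tests in this part were chosen after the results were seen, except the fit between the classes of sugars.

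Bbr_1865, Bbr_1866 and Bbr_1867 differed between the galactosides and the other sugars in the test of the difference itself, by -4.07, -4.65 and -3.65 on the log2 scale, values that rest partly on signals near background (bounds of 7.16, 10.2 and 5.05-fold in the channel recorded as ribose). The probes named rRNA16s and CDS lie outside the gene comparisons. They were well above background in 88.3% and 97.2% of their spots and channels, against 0 of 948 for the negative controls. For rRNA16s the log2 ratio was 1.35 on melezitose and 1.37 on stachyose, and -0.35 on melibiose.

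The channel recorded as sugar varied less between arrays than the channel recorded as ribose. Dye bias is argued against by the dye-swap array, whose channel recorded as sugar (Cy5) was closer to the Cy3 channel of the other slides than its own Cy3 channel was, by 0.0624 in r (0.966 against 0.904). Exchanged channel labels on every array stay open: the higher r in the channel recorded as sugar, in 15 of 15 pairs of arrays, is the pattern itself and decides nothing. Ribose cultures that differed between arrays, beside sugar cultures that did not, cannot be told apart from an exchange: the galactosyl split called 3 loci and the highest count among the other splits of the 5 sugars into 3 and 2 was 0, but 10 splits are too few for a share under 0.05. The exchange is a hypothesis, under which the loci described as brighter in the channel recorded as ribose would be those higher on the sugar, and Bbr_1415 to Bbr_1419 higher on ribose.

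Bbr_0030 and Bbr_0100 differed between the channels on the 4 sugars with a fructosyl unit and not on melibiose, a pattern noticed in the values. The slide is argued against as the cause, since melezitose shared the slide of melibiose and the smaller difference between their log2 ratios at these loci was 3.95. In the channel recorded as ribose it was 14.2-fold, with the level of Bbr_0100 on melibiose, where 1 of 6 spots was well above background, held at the lowest such spot. The fructosyl unit may be the common feature, but it is absent from a single sugar, so it cannot be told apart from the melibiose array. In the fit of melibiose against the other 4 sugars, which assumes that the lone sample varies like the others, neither locus was called (limma adjusted p = 0.0955 for each).

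Of 24 loci past 3-fold the same way on melibiose and sucrose, 18 had the other sign on melezitose, 6 of them past 3-fold. On stachyose 12 of the 24 had the other sign and on raffinose 0. The slide is argued against, since melibiose correlated more with sucrose, on another slide, than with melezitose, on its own, by 0.744 in r. That r includes the chosen loci. Without these 24 loci, r was 0.629 with sucrose and -0.177 with melezitose. The opposite sign held for 17 of the 24 after median centring, which argues against intensity-dependent normalization as its only source. The sizes did depend on it: on melibiose, loci past 3-fold in the channel recorded as ribose went from 28 to 11. Its part in which loci passed 3-fold therefore stays open. A difference between the sugars, or in the state of the cultures at harvest, stays open and was not tested.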

How the results depend on the processing

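The alternatives were fixed before the data were examined, except normexp on the negative controls, the dim-probe filter restricted to complete genes and the comparison of levels within the channel recorded as ribose, which were added after. No value past 3-fold of a named locus tag changed sign under any alternative, and the loci called by either test kept their sign wherever they could be fitted. The scanner's processed ratios and the authors' value table both gave 124 loci past 3-fold on melibiose, 76 on melezitose, 37 on raffinose and 71 on sucrose, against 35, 26, 18 and 39. Offset 10 gave 40 on melezitose, 29 on raffinose and 73 on stachyose (48). Median centring gave 19 on melibiose and 156 on stachyose. No background correction gave 17 on stachyose, and normexp on the negative controls 42 on melezitose and 28 on stachyose. The methods' t-test over probes within an array, with prior settings chosen here, gave the main counts on each sugar at its p and ratio cutoffs, and also after Benjamini-Hochberg with the ratio cutoff. It passed every locus past 3-fold and, after Benjamini-Hochberg alone, 525 to 1124 genes per sugar, so the ratio cutoff alone fixes the agreement.

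Over the 5 sugars, 8 loci brighter in the channel recorded as sugar became 0 with both sets of processed ratios and 15 with the slide as a random block, whose estimated correlation was -0.31. Calls in the channel recorded as ribose went from 0 to 1 with offset 10, 5 with median centring, 4 with the dim-probe filter, 2 with that filter on complete genes and 8 with the random block. They ranged from 0 to 3 when a sugar or a sucrose array was left out. Between the classes, 3 loci became 0 with both sets of processed ratios, 0 with the dim-probe filter, which leaves these loci no value on the sugars where they were dim, and 50 with the slide as a fixed block, which called 11 the other way. The slide as a random block, with an estimated correlation of -0.81, left 3 and 0. Leaving out a sugar or a sucrose array gave 0 to 3, and 0 to 4 the other way. Leaving out melezitose or sucrose leaves that class a lone sample, assumed to vary like the rest. The cause was not tested for the other changes. The tests of functional gene lists and their alternatives were not run, since locus tags had no match in the reference table. Local background, with a median of 34 to 42, lay below the median of the negative controls, 108 to 599, so ratios of dim loci depend most on the correction.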

Other observations

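The tests in this part were chosen after the data were seen.

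Fits of each sugar against the other 4 assume that the lone sample varies like the rest, and a call in them cannot separate a sugar from its array. For melibiose, raffinose and sucrose the spread in these fits includes that of the stachyose array. A share under 0.05 of the 1863 genes had an unadjusted p under 0.05 for these sugars. A lack of calls is therefore no evidence that they did not differ. For melezitose limma called 5 loci, Bbr_1856 to Bbr_1860, the run already described for that array. It called 0 for melibiose, raffinose and sucrose, with 37, 1 and 10 genes at an unadjusted p under 0.05. For stachyose it called 153, of which 108 had a lower ratio than the mean of the other 4 sugars. The stachyose array was the one with median spot intensities of 341 and 744 in the channels recorded as sugar and ribose, and with 99.97% of spots well above background in the latter. Most called loci with a higher ratio on stachyose lay in the middle of the locus tag order, and most with a lower ratio towards its ends. The calls thus followed position, so they may not be separate results for single loci. The source of this pattern was not tested.

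The 20 tRNA genes had a median log2 ratio of -0.22 on melibiose, at the 1.33 percentile of 10000 random lists matched on intensity, and 0.10 on sucrose, at the 91.8 percentile. Melezitose lay at 63.9, raffinose at 10.8 and stachyose at 16.2. These percentiles take genes as the units within single sugars, so they only describe the arrays. A single tRNA gene passed 3-fold on any sugar, tRNA-Cys on stachyose with a log2 ratio of 1.96. Probes for spike-ins, plasmids and iss1 were well above background in 0 of their spots on any array.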
